A study of Orbilia oligospora ATCC 24927 with 24 samples.

How the data were processed

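RNA-seq of hyphae of Arthrobotrys oligospora grown on potato dextrose agar at 28 °C was analysed in 24 libraries, 3 in each of 8 groups. Each of 2 experiments had its own wild type and 1 strain labelled as a deletion, sampled untreated (0 h) and after 12 h of trap induction with nematode extract. Groups and replicate numbers were taken from the sample titles.

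Gene expression was deposited by the authors as TPM (length-normalized transcript abundance) for every library, as the files' titles and the equal column sums say. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build was not given in the sources used here, so no coordinates are printed. TPM have the same sum in every library and keep no read counts, so the sequencing depth behind each value is unknown. An exact 0 in such values can be a failed estimate, and genes are therefore said to be listed at 0. The authors' deposited tables of comparisons hold log2 fold changes and adjusted p-values, per the file headers; the tool behind them was not given in the sources used here. The expression files also hold gene length, which in 99.98% of annotated genes was a multiple of 3 and so a coding length. The authors' deposited files of correlations between libraries were not used, nor were 8 columns of the authors' group means.

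The PkaC1 experiment's expression file held 13047 entries, of which 11479 were annotated genes and 1568 assembled loci without a gene name. The file of the Acy experiment held the same 11479 genes and no such loci. All 11479 names matched a locus tag of the RefSeq annotation. The annotation in the files gave a Swiss-Prot match for 5919 genes, a Pfam domain for 7441 and a KEGG orthologue for 4042. Assembled loci took 1.69% to 2.77% of the TPM of a library in the PkaC1 experiment and were left out of the main comparisons. The median TPM of annotated genes was 7.34 to 17.5 in libraries of the PkaC1 experiment and 14.4 to 25.0 in those of the Acy experiment.

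Annotated genes at 1 TPM or more in at least 3 of the 12 libraries of an experiment were tested, which left 8977 genes in the PkaC1 experiment and 9617 in the Acy experiment. Values were set to log2(TPM + 1), and fold changes are on that scale, which understates the change of low genes. Group means of all 4 groups of an experiment were fitted with limma (limma-trend, empirical Bayes), and adjusted p is Benjamini-Hochberg over all tested genes of a comparison. A gene is called at adjusted p under 0.05, and the number also changed 2-fold or more is given beside it. Per experiment the comparisons were deletion against wild type at each time, induction in each strain, and the difference between both induction responses. A joint fit of all 24 libraries over 9843 genes tested the difference of deletion effects between the experiments, and of wild type responses, the latter added after the values had been seen. Correlations of fold changes between the experiments used 8751 genes tested in both. Those within an experiment used its 8977 (PkaC1) or 9617 (Acy) tested genes.

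Before the data were examined, 35 gene lists were fixed by words in the annotation, of which 34 had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. The genes to be named were also fixed then. They are the candidates for the deleted genes; per comparison the 5 largest increases and 5 largest decreases among called genes with an annotated name, a mean of 10 TPM or more in the higher group and no overlap between groups; and up to 2 genes in each direction from the up to 6 lists with most called members. For differences between responses the rule has no condition on overlap. The text gives a part of these genes, and members of the polyketide cluster beyond them were chosen after their values were seen.

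Alternatives fixed at the same time were a pseudocount of 0.1, no filter on low values, a minimum of 5 TPM, libraries scaled to the same median, the replicate number as a block, limma with robust variances, only the 2 groups compared, and each library left out in turn. Added after the data were seen were each wild type group of the PkaC1 experiment as 1 library (the mean of its log2 values, with the spread taken from the other groups), the assembled loci in the fit, and lists matched without orthologous group (COG) text. Whether replicate numbers pair libraries was checked from the correlation of their deviations from the group means. Only the untreated and induced Acy deletion libraries had all 3 pairs above 0.1 (r = 0.137 to 0.435), and 2 of the 3 correlated best with their own number.

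The scripts were tested on simulated data with known changes. In the induced comparison of the PkaC1 experiment 62% of genes changed by 0.5 on the log2 scale and 90% of those changed by 1 were recovered, with 10 unchanged genes called among 8977. In that of the Acy experiment 18% and 84% were recovered, with 3 unchanged genes called among 9617. Simulated genes were independent, with the same spread in every group and no library-wide shift. Only genes above 10 TPM in untreated wild type were changed. The real groups differed in spread and in library medians, so these rates hold for the simulated setting only. R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used.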

Results

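Transcript levels were measured by RNA-seq in hyphae of the nematode-trapping fungus Arthrobotrys oligospora (ATCC 24927), in 24 libraries from 2 experiments. Each experiment set its own wild type against a strain labelled as a deletion, of AoPkaC1 (a catalytic subunit of cAMP-dependent protein kinase, PKA) or of AoAcy (adenylate cyclase). Every strain was sampled untreated (0 h) and after 12 h of trap induction with nematode extract, with 3 libraries per group. No group was sampled untreated at 12 h, so each change on induction also holds 12 h of further time. The extract and that time cannot be told apart here. Between 9461 and 9799 annotated genes were above 0 TPM in a library of the PkaC1 experiment, and between 10216 and 10539 in a library of the Acy experiment. Across genes, which are not independent replicates, libraries of the same group correlated at 0.971 to 0.993 in the PkaC1 experiment and at 0.968 to 0.991 in the Acy experiment. Libraries of different groups correlated at 0.7565 to 0.9127 and at 0.8568 to 0.9746, so in the Acy experiment the ranges overlap. A value given as ± is the SD after a TPM mean and the SE after a log2 fold change, with n = 3 libraries per group throughout.

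Replicate libraries of the wild type in the PkaC1 experiment lay closer together than those of any other group. Among genes at 1000 TPM or more, the median coefficient of variation was 1.63% and 1.98% in its untreated and induced libraries, against 6.03% to 17.9% in the other 6 groups. The submitters' design text gives 3 biological replicates, but nothing in the sample labels says whether the 3 libraries of a group came from separate cultures. Every p-value therefore measures only the spread between libraries. All 4 groups of the experiment share 1 estimate of spread per gene, so induction of the PkaC1 deletion libraries also draws on the small wild type spread. The total of called annotated genes in each comparison that involves this wild type is given a second time, with each of its groups taken as 1 library. This alternative was chosen after the spread had been seen. Its spread then comes from the other groups alone, which are the PkaC1 deletion libraries within the experiment (4 residual degrees of freedom), and the lone libraries are assumed to vary like them. It is a test under that assumption and no check on the wild type replicates. List calls within the experiment that end in this way are named.

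**Figure D1:**
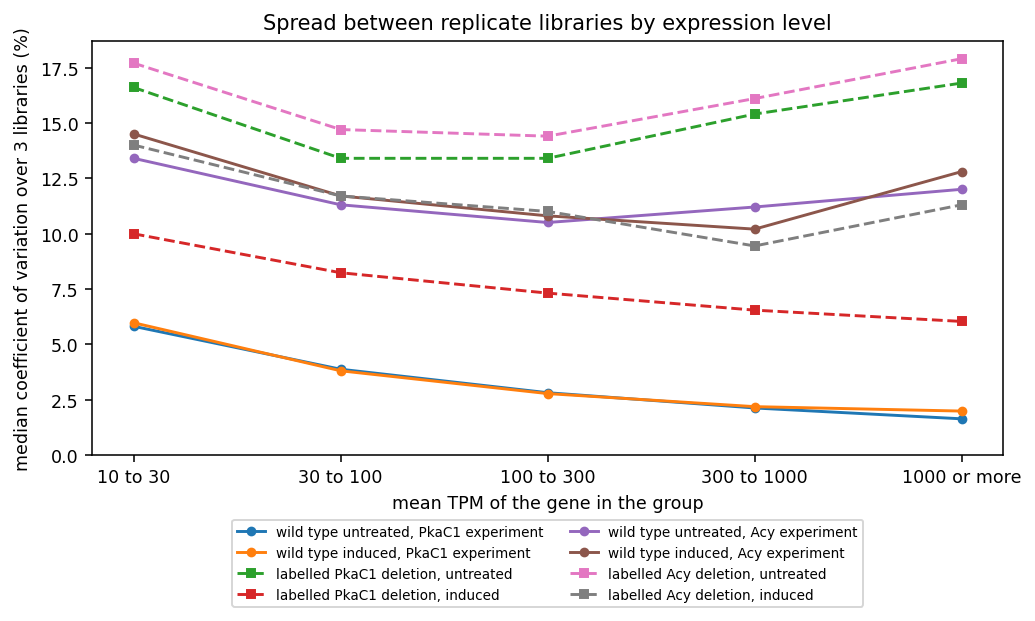
Median coefficient of variation (percent) over the 3 libraries of each group, for genes grouped by their mean TPM; solid lines are wild type groups and dashed lines are libraries labelled deletion. Both wild type groups of the PkaC1 experiment lie below the other 6 groups, at 1.63% and 1.98% for genes at 1000 TPM or more.

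The candidates for the deleted genes were still listed in every library labelled deletion. AOL_s00080g284, the annotated adenylate cyclase, fell from 16.5 ± 0.777 TPM in untreated wild type to 10.3 ± 0.906 TPM in the untreated Acy deletion libraries, 62.7% of wild type (log2 fold change -0.63 ± 0.153, limma adjusted p = 0.00536). After induction it was at 13.3 ± 2.14 and 11.6 ± 1.31 TPM (-0.18 ± 0.153, adjusted p = 0.32). With the libraries scaled to the same median the induced difference was -0.68 ± 0.109 (adjusted p = 0.000276). The authors' deposited table lists -0.82 and -0.60 for the same pairs. In the untreated PkaC1 deletion libraries, where AOL_s00080g284 is not the labelled target, it was at 149% of wild type (0.54, limma adjusted p = 0.00123). In the induced ones it was at 58.7% (-0.71, adjusted p = 0.000136). Scaling made these changes 0.31 and -0.27, and the untreated one in the Acy experiment -0.77.

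For the PKA catalytic subunit the annotation gives 2 genes, and the labels do not say which of them is AoPkaC1. AOL_s00043g480 was lower in the PkaC1 deletion libraries, at 48.5 ± 4.03 against 69.6 ± 0.943 TPM untreated (-0.51 ± 0.0754, adjusted p = 0.00011) and at 25.0 ± 0.0954 against 50.3 ± 3.79 TPM induced (-0.98 ± 0.0754, adjusted p = 7.44e-07). AOL_s00078g405 was at 51.2 ± 5.03 against 57.1 ± 1.1 TPM untreated (-0.16 ± 0.0799, adjusted p = 0.106) and at 25.0 ± 0.921 against 25.9 ± 1.57 TPM induced (-0.05, adjusted p = 0.61). Under scaling to the same median the untreated change of AOL_s00078g405 was -0.38 ± 0.0674 (adjusted p = 0.000476), and the induced one turned positive, at 0.39 ± 0.0674 (adjusted p = 0.000463). The authors' deposited table lists -0.50 and 0.46 for this gene (adjusted p = 3.94e-10 and 3.36e-07). For AOL_s00043g480 scaling left both changes negative, at -0.74 and -0.54, whereas the authors' deposited table lists -0.17 untreated and 0.22 induced. The TPM decrease of AOL_s00043g480 in the induced libraries is thus not shared by that table: the gap of 1.20 exceeded the median gap of 0.43 over 8909 genes, and 503 genes (5.65%) had a larger one. In the Acy experiment neither gene passed adjusted p 0.05 between the deletion and wild type libraries, with adjusted p = 0.839 and 0.126 for AOL_s00043g480 and 0.384 and 0.459 for AOL_s00078g405. Scaling turned the induced change there from 0.33 to -0.17 for AOL_s00043g480 and from 0.16 to -0.34 for AOL_s00078g405.

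**Figure D2:**
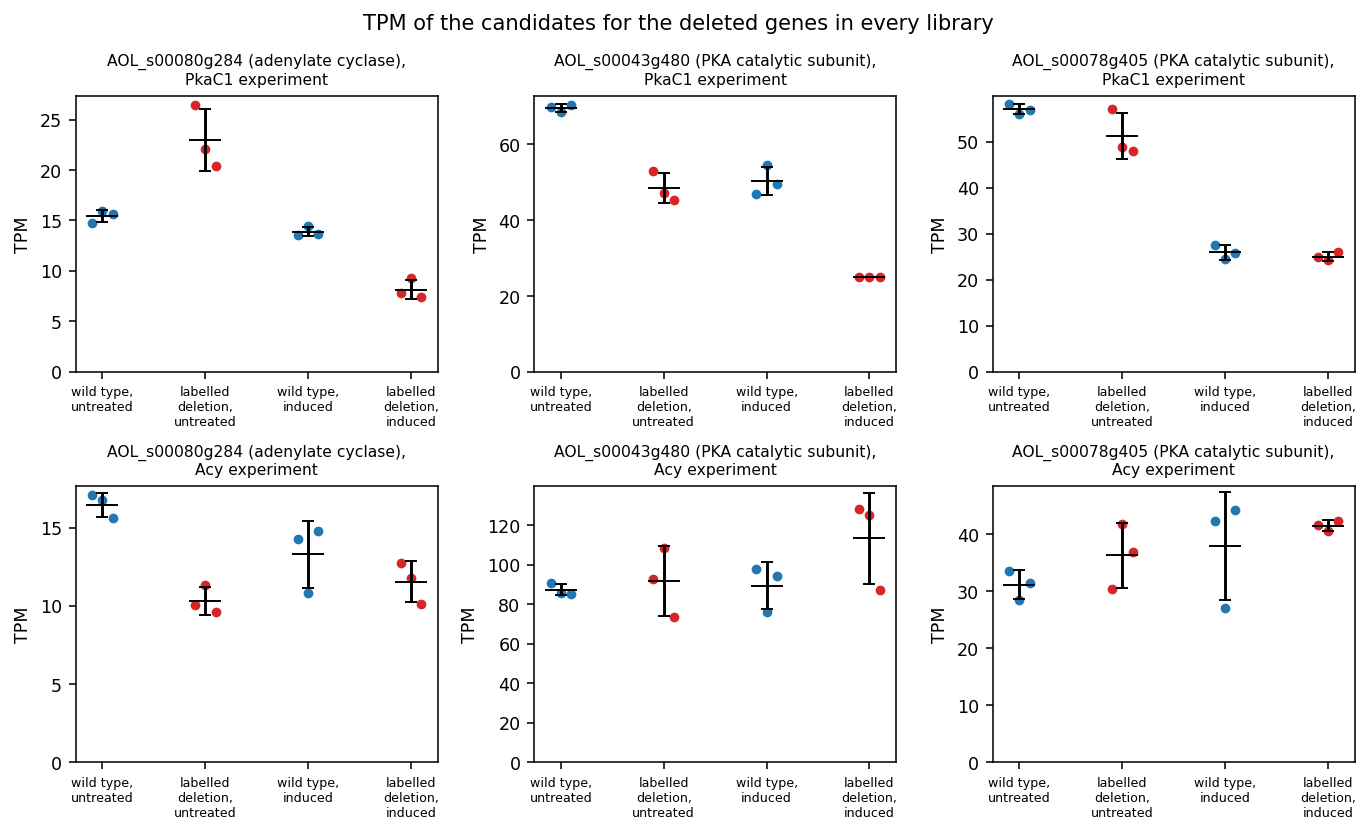
TPM of the annotated adenylate cyclase and of both PKA catalytic subunit genes in each library (points), with group mean and SD (black), for the PkaC1 experiment (top) and the Acy experiment (bottom). The adenylate cyclase stays at 62.7% of wild type in the untreated Acy deletion libraries, and AOL_s00043g480 at 49.7% in the induced PkaC1 deletion libraries.

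Between 480 and 7327 genes passed limma's adjusted p 0.05 in the 8 comparisons of 2 groups. TPM are shares of a library, and the median log2 fold change of all tested genes was away from 0 in most comparisons. In the PkaC1 experiment it was 0.20 (deletion against wild type, untreated), -0.39 (induced), -0.16 (induction of wild type) and -0.72 (induction of the deletion libraries), and after scaling the libraries to the same median -0.03, 0.04, 0.06 and 0.16. In the Acy experiment the 4 values were 0.11, 0.39, -0.19 and 0.09, and -0.04, -0.11, 0.04 and -0.03 after scaling. The direction of a majority of small changes depends on this scaling, and the split of all called genes is given both ways for each comparison. At adjusted p under 0.05 and 2-fold or more, the authors' deposited tables share 1263 to 2612 genes per comparison with the present fit in the PkaC1 experiment and 192 to 1711 in the Acy experiment. The balance of all calls at these thresholds differed in direction in 2 comparisons, in which scaling turned it. For the induced PkaC1 deletion against wild type the authors' deposited table has 1555 higher and 597 lower genes, against 731 and 1407 here, or 1322 and 465 after scaling. For induction of the PkaC1 deletion libraries the authors' deposited table has 1985 and 1754, against 810 and 3548 here, or 2168 and 1239 after scaling. In 2 others it differed only after scaling, with 918 and 1098 in the untreated PkaC1 comparison and 847 and 1254 in the induced Acy comparison, where the authors' deposited tables have 1189 and 1138, and 1210 and 1169. Of the shared genes all but 1 had the same direction, and the fold changes of the tables and the fit correlated across genes at 0.874 to 0.893 and at 0.934 to 0.952. Both rest on the same libraries, and the shared genes had passed in each, so this is no independent check. In the induced PkaC1 comparison the 1263 shared genes stood against 2138 called here and 2152 in the authors' deposited table.

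**Figure D3:**
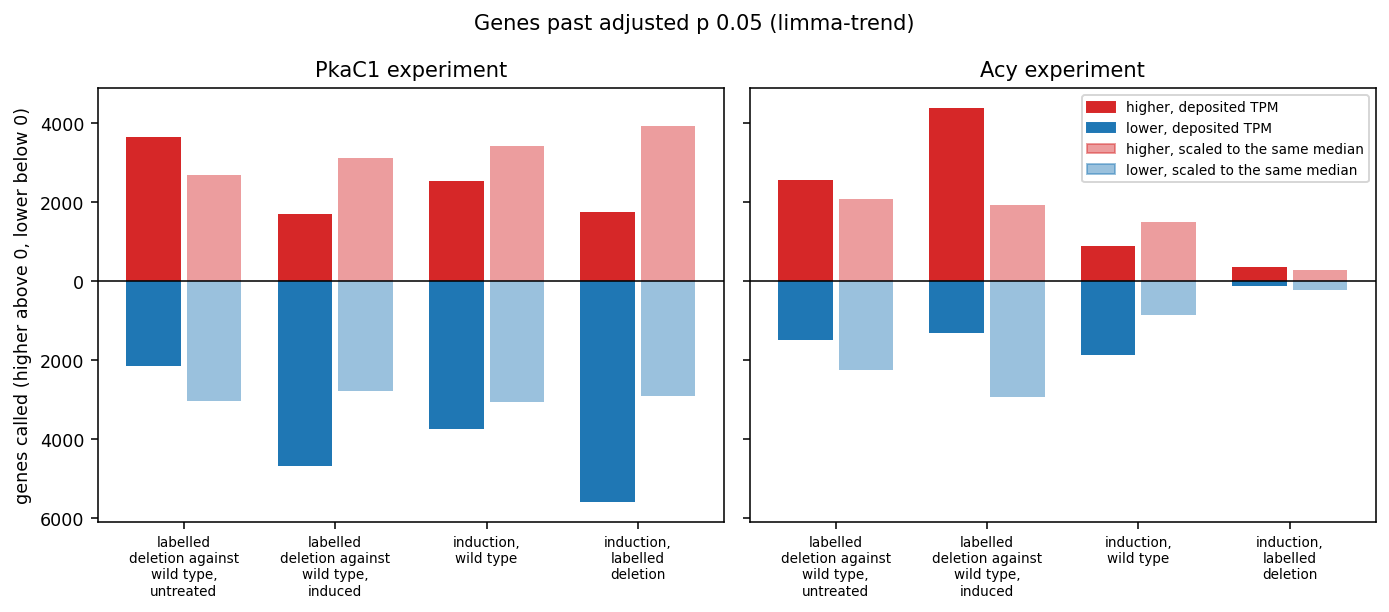
Number of genes past limma's adjusted p 0.05 in each comparison of 2 groups, higher above 0 and lower below 0, from the deposited TPM (dark) and with the libraries scaled to the same median (pale). The PkaC1 induced comparison changes from 1697 higher and 4671 lower to 3101 higher and 2788 lower, and the Acy one from 4378 and 1317 to 1914 and 2931.

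Each gene named in the following, other than the candidates for the deleted genes, members of the polyketide cluster, genes named for a difference between induction responses and genes said to be chosen after their values were seen, had all 3 libraries of the higher group above all 3 of the lower one. Chance gives this in 10% of genes. Protein names are those of Swiss-Prot matches or Pfam domains. A gene listed at 0 in all 3 libraries of a group is given no fold.

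In untreated PkaC1 deletion libraries 9 of 10 genes of the AOL_s00215 polyketide cluster were lower. The 6-methylsalicylic acid synthase AOL_s00215g283 went from 297 ± 4.17 to 5.85 ± 1.36 TPM (-5.46 ± 0.126, adjusted p = 4.71e-11), and the oxidoreductase AOL_s00215g277 from 1568 ± 22.2 to 41.5 ± 5.53 TPM (-5.21 ± 0.133, adjusted p = 1.07e-10). Cytochrome c (AOL_s00081g186) fell from 2838 ± 87.3 to 657 ± 36.8 TPM (-2.11 ± 0.062, adjusted p = 2.19e-10). Higher in the deletion libraries were a tyrosinase, AOL_s00215g501, from 0.603 ± 0.0987 to 159 ± 27.2 TPM (6.63 ± 0.139, adjusted p = 2.24e-11), and a zinc transporter, AOL_s00215g488, from 3.45 ± 1.02 to 133.5 ± 7.05 TPM (4.94 ± 0.146, adjusted p = 2.22e-10). A WSC-domain protein, AOL_s00080g412, rose from 7.95 ± 0.547 to 261 ± 12.9 TPM (4.87 ± 0.128, adjusted p = 1.25e-10). The short-chain dehydrogenase AOL_s00083g273 was listed at 0 in wild type and reached 335.5 ± 117.0 TPM, while the ribosome maturation protein AOL_s00097g296 went from 59.3 TPM to being listed at 0. Both genes were also listed at 0 in the induced libraries of wild type and deletion, so these zeros are not particular to 1 strain. In all, 5807 of 8977 genes were called, 3652 higher and 2155 lower (2677 and 3030 after scaling), 2077 of them at 2-fold or more. With each wild type group taken as 1 library, 3001 were called, 2998 of them among the 5807.

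In these libraries mitochondrial respiration had 65 of 105 tested genes lower, 11 higher and 29 not called (77 called when adjusted over the list alone, median log2 fold change -0.42, camera adjusted p = 8.58e-09, and 0.541 with an estimated correlation). In the tricarboxylic acid cycle 15 of 30 were lower and 2 higher (17 adjusted over the list alone, adjusted p = 0.000453, and 0.541 with an estimated correlation). The glyoxylate cycle and gluconeogenesis had 8 of 11 lower (8 adjusted over the list alone, adjusted p = 0.000453, and 0.366 with an estimated correlation). Trehalose and glycogen had 11 of 18 lower and 2 higher (13 adjusted over the list alone, adjusted p = 0.00278, and 0.413 with an estimated correlation). Cell cycle and mitosis had 139 of 218 genes higher and 24 lower (163 adjusted over the list alone, median 0.51, camera adjusted p = 0.000993, and 0.916 with an estimated correlation), among them the PHO85 cyclin AOL_s00078g9, from 91.0 ± 10.3 to 931 ± 155.0 TPM. That cyclin gene was listed at 0 in induced wild type and at 35.9 TPM in the induced deletion libraries. DNA replication had 40 of 61 higher and 4 lower (44 adjusted over the list alone, adjusted p = 0.0298, and 0.916 with an estimated correlation), or 31 and 8 after scaling. Cytosolic ribosomal proteins had 40 of 78 higher and 3 lower (41 adjusted over the list alone, adjusted p = 0.0316, and 0.916 with an estimated correlation), which scaling changed to 20 and 8 (adjusted p = 0.0914). With each wild type group as 1 library the calls of DNA replication and ribosomal proteins were lost (adjusted p = 0.0607 and 0.0988). The other called lists were lower. One was oxidative stress defence (35 of 93 lower, 23 higher, 56 adjusted over the list alone, adjusted p = 0.0194, and 0.541 with an estimated correlation, 48 and 15 after scaling). Nitrogen use from nitrate, urea and purines was another (12 of 23 lower, 4 higher, 16 adjusted over the list alone, adjusted p = 0.0194, and 0.714 with an estimated correlation). Peroxisome and fatty acid oxidation followed (29 of 73 lower, 19 higher, 49 adjusted over the list alone, adjusted p = 0.0224, and 0.916 with an estimated correlation, 37 and 14 after scaling). Autophagy had 17 of 30 genes higher and 5 lower (10 and 9 after scaling) and conidiation regulators 18 of 34 higher and 3 lower (14 and 6 after scaling), and neither list passed (adjusted p = 0.206 and 0.106). The camera test compares a list with all other genes, and lists matched by annotation text also hold some proteins that their name does not describe.

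In the induced PkaC1 deletion libraries cytosolic ribosomal proteins had 74 of 78 genes lower and 1 higher than in wild type (76 called when adjusted over the list alone, median -0.93, adjusted p = 6.68e-06, and 0.716 with an estimated correlation). The proteasome had 45 of 48 lower and 2 higher (47 adjusted over the list alone, median -0.89, adjusted p = 6.9e-05, and 0.716 with an estimated correlation). Ribosome biogenesis had 77 of 90 lower and 5 higher (83 adjusted over the list alone, median -0.92, adjusted p = 9.31e-05, and 0.716 with an estimated correlation). Sterol biosynthesis had 21 of 28 lower and 3 higher (24 adjusted over the list alone, median -1.22, adjusted p = 0.0012, and 0.716 with an estimated correlation), or 15 and 6 after scaling. Vesicle trafficking had 115 of 150 lower and 7 higher (123 adjusted over the list alone, adjusted p = 0.000298, and 0.716 with an estimated correlation). Mitochondrial respiration had 83 of 105 lower and 8 higher (92 adjusted over the list alone, adjusted p = 0.0049, and 0.716 with an estimated correlation). Actin, septin and endocytosis had 87 of 121 lower and 13 higher (101 adjusted over the list alone, adjusted p = 0.0156, and 0.848 with an estimated correlation). After scaling these were 73 and 20, 51 and 16, and 57 and 27. The glyoxylate cycle and gluconeogenesis went the other way, with 9 of 11 higher and 2 lower (11 adjusted over the list alone, median 0.64, adjusted p = 6.9e-05, and 0.434 with an estimated correlation, 9 and 0 after scaling). Against the respiration list as a whole, the alternative oxidase AOL_s00080g303 rose from 233 ± 10.5 to 915 ± 97.8 TPM (1.97 ± 0.125, adjusted p = 1.68e-07).

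After induction the transferase AOL_s00215g276 of the cluster went from 589 ± 13.1 to 3.43 ± 1.64 TPM (-7.14 ± 0.305, adjusted p = 7.69e-09). Upward, a GPI-anchored cupredoxin, AOL_s00097g587, rose from 4.26 ± 2.03 to 239 ± 17.9 TPM (5.58 ± 0.211, adjusted p = 3.01e-09) and conidiation-specific protein 13 (AOL_s00081g178) from 0.307 ± 0.472 to 46.4 ± 15.0 TPM (5.19 ± 0.361, adjusted p = 3.39e-07). The endochitinase AOL_s00079g59 rose from 12.5 ± 1.08 to 199.8 ± 2.95 TPM (3.90 ± 0.0674, adjusted p = 3.75e-11). Argininosuccinate lyase (AOL_s00215g119) went from 93.0 TPM to being listed at 0. Of 8977 genes 6368 were called, 1697 higher and 4671 lower (3101 and 2788 after scaling), 2138 at 2-fold or more. With each wild type group taken as 1 library 3918 were called, 3916 of them among the 6368. In 5 lists camera found members high against the other genes although higher and lower genes were about as many. These were NADPH oxidase and melanin (12 of 28 higher, 9 lower, 23 adjusted over the list alone, adjusted p = 0.0156, and 0.716 with an estimated correlation) and adhesion, lectins and surface proteins (31 of 87 higher, 37 lower, 68 adjusted over the list alone, median -0.01, mean 0.14, adjusted p = 0.0156, and 0.716 with an estimated correlation). Also among them were nutrient transporters (23 of 69 higher, 24 lower, 47 adjusted over the list alone, adjusted p = 0.0163, and 0.716 with an estimated correlation) and chitinases and glucanases (23 of 75 higher, 27 lower, 50 adjusted over the list alone, median -0.08, mean 0.04, adjusted p = 0.0163, and 0.716 with an estimated correlation). The last was peroxisome and fatty acid oxidation (24 of 73 higher, 26 lower, 50 adjusted over the list alone, median -0.10, mean 0.13, adjusted p = 0.0211, and 0.848 with an estimated correlation). After scaling the higher genes led in all 5, with 17 and 3, 41 and 22, 34 and 14, 39 and 14, and 41 and 11, but adhesion, lectins and surface proteins were no longer called (adjusted p = 0.0564). Autophagy (19 of 30 lower, 4 higher, 12 and 9 after scaling, adjusted p = 0.279) and conidiation regulators (15 of 34 lower, 9 higher, but 7 and 15 after scaling, adjusted p = 0.19) were not called.

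On induction in the wild type of the PkaC1 experiment the cytosolic ribosomal proteins had 75 of 78 genes higher and 1 lower (76 adjusted over the list alone, median 1.90, camera adjusted p = 4.9e-25, and 0.898 with an estimated correlation). By its annotation text this list also holds a tyrosinase (AOL_s00210g370, from 8.02 ± 0.477 to 47.2 ± 2.99 TPM) and a ubiquitin ligase (AOL_s00079g260, from 61.5 ± 3.21 to 51.0 ± 1.62 TPM), both singled out after their values were seen. The beta-glucosidase AOL_s00083g367 rose from 0.417 ± 0.15 to 349 ± 6.1 TPM (7.95 ± 0.14, adjusted p = 6.68e-12) and phosphoglycerate dehydrogenase AOL_s00215g666 from 1.07 ± 1.19 to 259 ± 3.29 TPM. Argininosuccinate synthase (AOL_s00076g641) was listed at 0 before and at 279 ± 12.3 TPM after. The coat protein gene AOL_s00215g248 (SEC24) fell from 221.5 ± 10.9 to 10.7 ± 2.75 TPM (-4.28 ± 0.18, adjusted p = 2.29e-09). Ribosome biogenesis had 49 of 90 higher and 6 lower (52 adjusted over the list alone, adjusted p = 2.99e-06, and 0.898 with an estimated correlation). Mitochondrial respiration had 59 of 105 higher and 12 lower (71 adjusted over the list alone, adjusted p = 2.99e-06, and 0.898 with an estimated correlation). The tricarboxylic acid cycle had 23 of 30 higher and 5 lower (29 adjusted over the list alone, adjusted p = 1.69e-05, and 0.898 with an estimated correlation). Sterol biosynthesis had 16 of 28 higher and 7 lower (23 adjusted over the list alone, adjusted p = 0.00316, and 0.898 with an estimated correlation). Nitrogen use had 18 of 23 lower and 1 higher (19 adjusted over the list alone, adjusted p = 0.000533, and 0.898 with an estimated correlation). In total 6258 genes were called, 2526 higher and 3732 lower (3427 and 3058 after scaling), 2928 at 2-fold or more. With each wild type group as 1 library, so that the spread came from the deletion libraries alone, 3343 were called, 3340 of them shared.

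In the PkaC1 deletion libraries induction called 7327 genes, 1740 higher and 5587 lower (3911 and 2912 after scaling), 4358 at 2-fold or more. The aldolase AOL_s00083g372 rose from 1.97 ± 0.517 to 309 ± 24.7 TPM (6.72 ± 0.134, adjusted p = 1.09e-11) and heat shock protein hsp88 (AOL_s00210g139) from 401.5 ± 84.8 to 2494 ± 276 TPM (2.65 ± 0.126, adjusted p = 4.03e-09). The septin AOL_s00215g893 fell from 28.7 ± 8.87 to 0.487 ± 0.485 TPM (-4.33). Ribosomal proteins (66 of 78 higher, 3 lower, 69 adjusted over the list alone, median 0.62, adjusted p = 2.88e-17) and the tricarboxylic acid cycle (22 of 30 higher, 3 lower, 25 adjusted over the list alone, adjusted p = 4.63e-11) rose here too. Their adjusted p was 0.905 and 0.122 with an estimated correlation. Mitochondrial respiration had 47 of 105 higher and 27 lower (74 adjusted over the list alone, adjusted p = 1.07e-08, and 0.905 with an estimated correlation), or 91 and 4 after scaling. The glyoxylate list had 10 of 11 higher and 1 lower (11 adjusted over the list alone, median 1.70, adjusted p = 4.47e-08, and 0.114 with an estimated correlation). Cell cycle and mitosis had 192 of 218 lower and 6 higher (198 adjusted over the list alone, median -1.17, adjusted p = 8.46e-05, and 0.991 with an estimated correlation). The proteasome had 46 of 48 lower and 1 higher (47 adjusted over the list alone, adjusted p = 0.000464, and 0.991 with an estimated correlation). Vesicle trafficking had 119 of 150 lower and 10 higher (129 adjusted over the list alone, adjusted p = 0.00203, and 0.991 with an estimated correlation). Actin, septin and endocytosis had 94 of 121 lower and 16 higher (112 adjusted over the list alone, adjusted p = 0.0224, and 0.991 with an estimated correlation). After scaling the splits of these 4 lists were 112 and 45, 30 and 9, 71 and 42, and 65 and 37. Peroxisome (32 of 73 higher, 30 lower, 62 adjusted over the list alone, median -0.11, mean 0.14, adjusted p = 0.000328, and 0.991 with an estimated correlation) and oxidative stress defence (35 of 93 higher, 32 lower, 67 adjusted over the list alone, median -0.06, mean -0.03, adjusted p = 0.000408, and 0.338) were high against other genes. After scaling they had 53 and 11, and 64 and 19.

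Tested directly, the induction responses of PkaC1 deletion and wild type libraries differed for 6458 genes, 1618 with a higher and 4840 with a lower response in the deletion libraries (3079 and 2685 after scaling), 3845 by 2-fold or more. With each wild type group as 1 library the count was 3931, of which 3929 were shared. A glucose-repressible protein, AOL_s00004g152, fell from 1705 ± 72.4 to 49.2 ± 10.7 TPM in wild type. It rose from 103.6 ± 37.3 to 706 ± 109 TPM in the deletion libraries (difference 7.93 ± 0.354, adjusted p = 1.47e-08). The NmrA-like gene AOL_s00215g876 rose from 5.35 ± 0.869 to 190.3 ± 4.28 TPM in wild type. It fell from 117 ± 33.4 to 10.9 ± 1.3 TPM in the deletion libraries (-8.20 ± 0.239, adjusted p = 8.78e-10). The response was lower for 75 of 78 ribosomal protein genes and higher for none (75 adjusted over the list alone, median -1.28, adjusted p = 4.87e-06, and 0.855 with an estimated correlation). The same held for 42 of 48 proteasome genes (43 adjusted over the list alone, adjusted p = 0.000135, and 0.855 with an estimated correlation). It was also lower for 77 of 90 ribosome biogenesis genes against 3 higher (82 adjusted over the list alone, adjusted p = 0.00119, and 0.855 with an estimated correlation). For cell cycle genes it was lower for 163 of 218 against 17 (182 adjusted over the list alone, adjusted p = 0.00299, and 0.855 with an estimated correlation). After scaling the latter pair were at 42 and 11, and 101 and 41. It was higher for 9 of 11 glyoxylate genes and lower for 2 (11 adjusted over the list alone, median 1.37, adjusted p = 1.9e-06, and 0.171 with an estimated correlation, 10 and 0 after scaling). The 12 called lists also include peroxisome (22 of 73 higher, 23 lower, but 48 and 8 after scaling, 43 adjusted over the list alone, adjusted p = 0.000287, and 0.855 with an estimated correlation) and the tricarboxylic acid cycle (13 of 30 higher, 10 lower, 23 adjusted over the list alone, median 0.15, mean -0.06, adjusted p = 0.0128, and 0.855 with an estimated correlation, 18 and 5 after scaling). DNA replication was lower (43 of 61 lower, 3 higher, 47 adjusted over the list alone, adjusted p = 0.0251, and 0.855 with an estimated correlation, 33 and 14 after scaling). Trehalose and glycogen had 9 of 18 higher and 7 lower (16 adjusted over the list alone, adjusted p = 0.0251, and 0.855 with an estimated correlation, 10 and 5 after scaling). Vesicle trafficking had 110 of 150 lower and 15 higher (126 adjusted over the list alone, adjusted p = 0.0128, and 0.855 with an estimated correlation, 67 and 37 after scaling). Scaling ended both calls (adjusted p = 0.0885 and 0.0541).

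Untreated Acy deletion libraries differed from their wild type in 4051 of 9617 genes, 2554 higher and 1497 lower (2067 and 2255 after scaling), 1744 at 2-fold or more. The serine protease inhibitor AOL_s00076g558 fell from 715 ± 92.8 to 12.0 ± 3.29 TPM (-5.82 ± 0.307, adjusted p = 2.78e-08) and a lipoxygenase, AOL_s00097g288, from 141 ± 43.9 to 4.43 ± 1.4 TPM (-4.70 ± 0.34, adjusted p = 4.51e-07). The cluster's AOL_s00215g277 fell from 299 ± 56.7 to 12.2 ± 7.84 TPM (-4.70 ± 0.426, adjusted p = 2.77e-06). Up went a cytochrome P450, AOL_s00081g120, from 2.34 ± 1.06 to 99.2 ± 23.6 TPM (4.94 ± 0.318, adjusted p = 1.54e-07), and an acyl-CoA ligase, AOL_s00076g158, from 161 ± 34 to 3243 ± 94.1 TPM (adjusted p = 1.1e-09). A manganese superoxide dismutase, AOL_s00170g93, rose from 3.32 ± 0.222 to 76.4 ± 26.3 TPM (4.11 ± 0.258, adjusted p = 1.34e-07). Lectins moved both ways, with AOL_s00006g511 rising from 176 ± 63.7 to 904 ± 189 TPM (2.41 ± 0.301, adjusted p = 3.98e-05) and AOL_s00080g288 falling from 247 ± 78.5 to 36.5 ± 3.56 TPM (-2.68 ± 0.277, adjusted p = 7.96e-06).

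Mitochondrial respiration was lower in these libraries, with 61 of 105 genes lower, 4 higher and 40 not called (70 called when adjusted over the list alone, median -0.46, adjusted p = 8.48e-10, and 0.497 with an estimated correlation). Trehalose and glycogen had 10 of 18 lower and 3 higher (14 adjusted over the list alone, median -0.82, adjusted p = 0.00184, and 0.96 with an estimated correlation). The tricarboxylic acid cycle had 11 of 30 lower and 3 higher (17 adjusted over the list alone, adjusted p = 0.00207, and 0.96 with an estimated correlation, 19 and 2 after scaling). Few ribosomal protein genes passed singly, 7 of 78 lower and none higher (1 adjusted over the list alone), while the list did (median -0.29, adjusted p = 2.45e-05, and 0.96 with an estimated correlation). Ribosome biogenesis was called as well (21 of 94 lower, 8 higher, 28 adjusted over the list alone, adjusted p = 0.00714, and 0.96 with an estimated correlation, 33 and 6 after scaling). Autophagy (10 of 31 higher, 4 lower, 6 and 6 after scaling, adjusted p = 0.885) and conidiation regulators (12 of 34 higher, 6 lower, adjusted p = 0.564) were not called.

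After induction 5695 genes differed between Acy deletion and wild type libraries, 4378 higher and 1317 lower (1914 and 2931 after scaling), 2327 at 2-fold or more. The P450 AOL_s00078g25 rose from 2.41 ± 0.409 to 209.8 ± 34.7 TPM (5.95 ± 0.18, adjusted p = 1.4e-10) and the methionine permease AOL_s00054g977 from 2.34 ± 0.312 to 199 ± 34.8 TPM (5.89 ± 0.175, adjusted p = 1.4e-10). The oligopeptide transporter AOL_s00188g351 fell from 494 ± 44.6 to 4.94 ± 2.67 TPM (-6.47 ± 0.336, adjusted p = 1.79e-08) and the lectin AOL_s00080g288 from 1617 ± 596 to 43.1 ± 5.81 TPM (-5.12 ± 0.277, adjusted p = 2.4e-08). The aspergillopepsin AOL_s00054g264 fell from 301 ± 39.6 to 22.6 ± 14.4 TPM (-3.83). Respiration was again lower, with 53 of 105 genes lower and 7 higher (60 adjusted over the list alone, median -0.45, adjusted p = 3.42e-14, and 0.362 with an estimated correlation). Cell cycle and mitosis had 167 of 228 higher and 5 lower (177 adjusted over the list alone, adjusted p = 4.82e-05, and 0.696 with an estimated correlation). DNA repair had 64 of 84 higher and 2 lower (68 adjusted over the list alone, adjusted p = 0.00403, and 0.696 with an estimated correlation). DNA replication had 46 of 65 higher and 4 lower (53 adjusted over the list alone, adjusted p = 0.0115, and 0.696 with an estimated correlation). The proteasome had 42 of 51 higher and 1 lower (45 adjusted over the list alone, adjusted p = 0.00519, and 0.696 with an estimated correlation). Scaling left 72 and 18, 30 and 11, 14 and 8, and 10 and 4, with the proteasome no longer called (adjusted p = 0.131). Trehalose and glycogen (8 of 18 lower, 4 higher, 13 adjusted over the list alone, adjusted p = 0.000679, and 0.696 with an estimated correlation) and nitrogen use (11 of 24 lower, 6 higher, 17 adjusted over the list alone, adjusted p = 0.00618, and 0.696 with an estimated correlation) were lower, at 13 and 1 each after scaling.

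In 3 other called lists of that comparison the majority of genes turned with the scaling. Oxidative stress defence had 28 of 100 genes higher and 26 lower, but 18 and 56 after scaling (52 adjusted over the list alone, median -0.03, mean 0.11, camera down, adjusted p = 0.00925, and 0.696 with an estimated correlation). Chitinases and glucanases had 29 of 86 higher and 25 lower, but 17 and 41 (54 adjusted over the list alone, median 0.02, mean 0.07, camera down, adjusted p = 0.00971, and 0.696 with an estimated correlation). Plant polysaccharide degradation had 49 of 133 higher and 27 lower, but 20 and 54 (76 adjusted over the list alone, median 0.17, camera down, adjusted p = 0.0344, and 0.696 with an estimated correlation). In the remaining lists the majority kept its direction. The tricarboxylic acid cycle (10 of 30 lower, 6 higher, 20 and 2 after scaling, 16 adjusted over the list alone, adjusted p = 0.00971, and 0.696 with an estimated correlation) and the glyoxylate list (3 of 13 lower, 1 higher, 9 and 0 after scaling, 4 adjusted over the list alone, adjusted p = 0.0115, and 0.696 with an estimated correlation) were lower. Heat shock proteins and chaperones were higher (61 of 120 higher, 6 lower, 35 and 25 after scaling, 67 adjusted over the list alone, adjusted p = 0.0448, and 0.85 with an estimated correlation). Scaling ended the calls of chitinases, plant polysaccharide degradation and heat shock proteins (adjusted p = 0.109, 0.125 and 0.144). Autophagy had 20 of 31 higher and 1 lower, but 6 and 8 after scaling (adjusted p = 0.292), and conidiation regulators 13 of 34 higher and 5 lower, but 7 and 13 after scaling (adjusted p = 0.554).

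Induction in the wild type of the Acy experiment called 2751 genes, 885 higher and 1866 lower (1497 and 855 after scaling), 804 at 2-fold or more. Without replicate 2 of the induced wild type 1690 were called. A glutathione transferase, AOL_s00080g183, rose from 0.717 ± 0.17 to 2758 ± 774 TPM (10.62 ± 0.584, adjusted p = 2.17e-07) and a xylulose reductase, AOL_s00007g195, from 0.0333 to 163 ± 54.1 TPM (7.25 ± 0.6, adjusted p = 5.09e-06). A rodlet protein, AOL_s00006g570, rose from 747 ± 184 to 7568 ± 992 TPM (3.36 ± 0.176, adjusted p = 1.5e-07) and the lectin AOL_s00080g288 from 247 to 1617 TPM (2.67 ± 0.277, adjusted p = 3.14e-05). Ribosomal proteins fell, with 59 of 78 genes lower and none higher (69 adjusted over the list alone, median -0.64, adjusted p = 2.52e-10, and 0.841 with an estimated correlation). AOL_s00097g596 (S25), for example, went from 7270 ± 778 to 3735 ± 961 TPM (-0.99 ± 0.221, adjusted p = 0.00647). After scaling 16 of the list were lower and none higher. Ribosome biogenesis had 45 of 94 lower and 1 higher (54 adjusted over the list alone, adjusted p = 8.93e-06, and 0.841 with an estimated correlation). Cell cycle and mitosis had 72 of 228 lower and 5 higher (81 adjusted over the list alone, adjusted p = 0.00165, and 0.841 with an estimated correlation, 37 and 15 after scaling). DNA replication had 28 of 65 lower and 2 higher (33 adjusted over the list alone, adjusted p = 0.00944, and 0.841 with an estimated correlation, 11 and 4 after scaling). Nutrient transporters had 17 of 73 higher and 6 lower (23 adjusted over the list alone, adjusted p = 0.000561, and 0.841 with an estimated correlation, 27 and 4 after scaling). Nitrogen use had 8 of 24 higher and 5 lower (16 adjusted over the list alone, adjusted p = 0.0114, and 0.841 with an estimated correlation, 13 and 3 after scaling). Oxidative stress defence had 14 of 100 higher and 9 lower (23 adjusted over the list alone, median -8e-04, mean 0.235, adjusted p = 0.00959, and 0.841 with an estimated correlation, 28 and 5 after scaling). Cell wall synthesis (13 of 50 lower, 2 higher, 6 and 3 after scaling, 17 adjusted over the list alone, adjusted p = 0.0267, and 0.841 with an estimated correlation) and endoplasmic reticulum folding (5 of 7 lower, none higher, 6 adjusted over the list alone, adjusted p = 0.0328, and 0.841 with an estimated correlation) were lower. Vesicle trafficking was lower too (41 of 153 lower, 3 higher, 14 and 9 after scaling, 44 adjusted over the list alone, adjusted p = 0.0328, and 0.841 with an estimated correlation), but not called after scaling (adjusted p = 0.135).

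Fewest genes changed on induction of the Acy deletion libraries, 480, of which 352 were higher and 128 lower (273 and 221 after scaling), 214 at 2-fold or more. The count moved with single libraries, to 156, 152 and 868 without replicate 1, 2 or 3 of the induced libraries and to 313 and 230 without replicate 1 or 2 of the untreated ones. With the replicate block it was 349, in the only pair of groups whose same-numbered libraries all correlated above 0.1. The glutathione transferase AOL_s00080g183 rose here as well, from 0.83 ± 0.267 to 1824 ± 1290 TPM (9.49 ± 0.584, adjusted p = 9.2e-06). Heat shock protein 90 (AOL_s00083g179) rose from 988 ± 214 to 2572 ± 960 TPM (1.32 ± 0.278, adjusted p = 0.0186) and an ammonium transporter, AOL_s00043g163, from 573 ± 144 to 1362 ± 390 TPM (1.23 ± 0.249, adjusted p = 0.0156). The lectin AOL_s00006g511 fell from 904 ± 189 to 229 ± 77.2 TPM (adjusted p = 0.00322). Heat shock proteins and chaperones had 12 of 120 genes higher and none lower (24 adjusted over the list alone, adjusted p = 0.000463, and 0.886 with an estimated correlation, 8 and 1 after scaling). Camera also called lists in which almost no gene passed singly. These were mitochondrial respiration (1 of 105 higher, 1 lower, none adjusted over the list alone, median -0.15, adjusted p = 1.42e-07, and 0.508 with an estimated correlation). Among them were also ribosomal proteins (0 of 78, median -0.13, adjusted p = 1.96e-05, and 0.886 with an estimated correlation) and the proteasome (0 of 51, median 0.23, adjusted p = 0.000843, and 0.886 with an estimated correlation).

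The induction response of the Acy deletion libraries differed from that of wild type for 1852 genes, 1362 with a higher and 490 with a lower response (457 and 961 after scaling), 1011 by 2-fold or more. Without replicate 1 or 2 of the induced deletion libraries the count was 851 or 874, without replicate 2 of the induced wild type 940, without replicate 3 of the untreated deletion libraries 1206 and without replicate 1 of the untreated wild type 1231. Methionine permease AOL_s00054g977 fell from 11.9 ± 2.06 to 2.34 ± 0.312 TPM in wild type. It rose from 60.1 ± 9.25 to 199 ± 34.8 TPM in the deletion libraries (3.65 ± 0.247, adjusted p = 1.1e-05). The rise of the rodlet protein AOL_s00006g570 in wild type had no counterpart in the deletion libraries, at 1298 ± 78.1 TPM before and 1124 ± 85.3 TPM after (-3.57 ± 0.249, adjusted p = 1.1e-05). Responses were higher for 58 of 228 cell cycle genes and lower for 3 (75 adjusted over the list alone, adjusted p = 0.00129, and 0.813 with an estimated correlation, 20 and 6 after scaling). For ribosome biogenesis genes the counts were 31 of 94 against 1 (37 adjusted over the list alone, adjusted p = 0.002, and 0.813 with an estimated correlation). Responses were also higher for 9 of 78 ribosomal protein genes (5 adjusted over the list alone, median 0.55, adjusted p = 0.002, and 0.813 with an estimated correlation, 1 and 1 after scaling). For heat shock genes the counts were 36 of 120 against 3 (49 adjusted over the list alone, adjusted p = 0.0132, and 0.813 with an estimated correlation, 15 and 4 after scaling). The other 8 of the 12 called lists also had adjusted p = 0.813 with an estimated correlation, and 3 of these were not called after scaling. The proteasome had 11 of 51 higher and 1 lower (15 adjusted over the list alone, adjusted p = 0.0132, and 0.813 with an estimated correlation, but 1 and 1 and adjusted p = 0.129 after scaling). Vesicle trafficking had 31 of 153 higher and 1 lower (36 adjusted over the list alone, adjusted p = 0.0231, and 0.813 with an estimated correlation, but 6 and 7 and adjusted p = 0.0934 after scaling). Adhesion, lectins and surface proteins had 12 of 96 higher and 14 lower (26 adjusted over the list alone, median 0.06, mean -0.15, camera down, adjusted p = 0.0235, and 0.813 with an estimated correlation, but 4 and 19 and adjusted p = 0.0934 after scaling).

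The AOL_s00215 polyketide cluster, 10 neighbouring genes fixed as a list, was lower in both deletion strains. Untreated, 9 of 10 genes were lower and none higher in the PkaC1 deletion libraries (9 adjusted over the list alone, median -4.76, camera adjusted p = 5.54e-08) and likewise 9 of 10 in the Acy deletion libraries (9 adjusted over the list alone, median -3.25, adjusted p = 3.25e-09). These had adjusted p = 0.366 and 0.497 with an estimated correlation. Induced, 9 were lower and 1 higher in the PkaC1 deletion libraries (10 adjusted over the list alone, median -5.85, adjusted p = 0.000468, and 0.716 with an estimated correlation), and 9 lower in the Acy deletion libraries (10 adjusted over the list alone, median -1.93, adjusted p = 5.53e-08, and 0.666). The exception was AOL_s00215g278, a cytochrome P450, which rose from 2155 ± 78.3 to 6104 ± 284 TPM in the induced PkaC1 deletion libraries (1.501 ± 0.142, adjusted p = 3.33e-06) and was at 1946 ± 123 and 2153 ± 493 TPM untreated (0.12, adjusted p = 0.478). For the untreated pair the authors' deposited table lists it as lower, at -1.35 (adjusted p = 3.84e-12). In the Acy experiment the same gene fell with its neighbours, from 79.2 ± 18.7 to 6.82 ± 2.48 TPM untreated (-3.39 ± 0.251, adjusted p = 5.62e-07). The gene of the cluster not called there was AOL_s00215g275, at 0.03 untreated (adjusted p = 0.955) and -0.74 induced (adjusted p = 0.0757). On induction 8 of the 10 genes were lower in the wild type of the Acy experiment (9 adjusted over the list alone, median -2.31, camera adjusted p = 8.48e-05, and 0.841 with an estimated correlation), and 3 in its deletion libraries (5 adjusted over the list alone, median -0.80, adjusted p = 4.75e-06, and 0.508). The latter response was higher than that of wild type for 6 genes (7 adjusted over the list alone, median 1.24, adjusted p = 0.0307, and 0.813 with an estimated correlation). Deletion values of these genes were low, and log2(TPM + 1) understates the fall of low genes. AOL_s00215g280 fell from 63.1 to 10.3 TPM in wild type and from 3.79 to 0.743 TPM in deletion libraries (1.05, limma adjusted p = 0.0296). For AOL_s00215g277 the falls were from 299 to 34.7 and from 12.2 to 7.52 TPM (2.68, adjusted p = 0.0125). In the PkaC1 experiment the list was not called on induction, with 5 genes lower and 1 higher in wild type (5 adjusted over the list alone, adjusted p = 0.665, 4 and 3 after scaling). In its deletion libraries 8 were lower and 1 higher (9 adjusted over the list alone, adjusted p = 0.58, 5 and 2 after scaling). The wild types differed in level, with AOL_s00215g283 at 297 ± 4.17 TPM in the untreated wild type of the PkaC1 experiment and at 14.3 ± 3.98 TPM in that of the Acy experiment, a difference between experiments that was not tested.

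**Figure D4:**
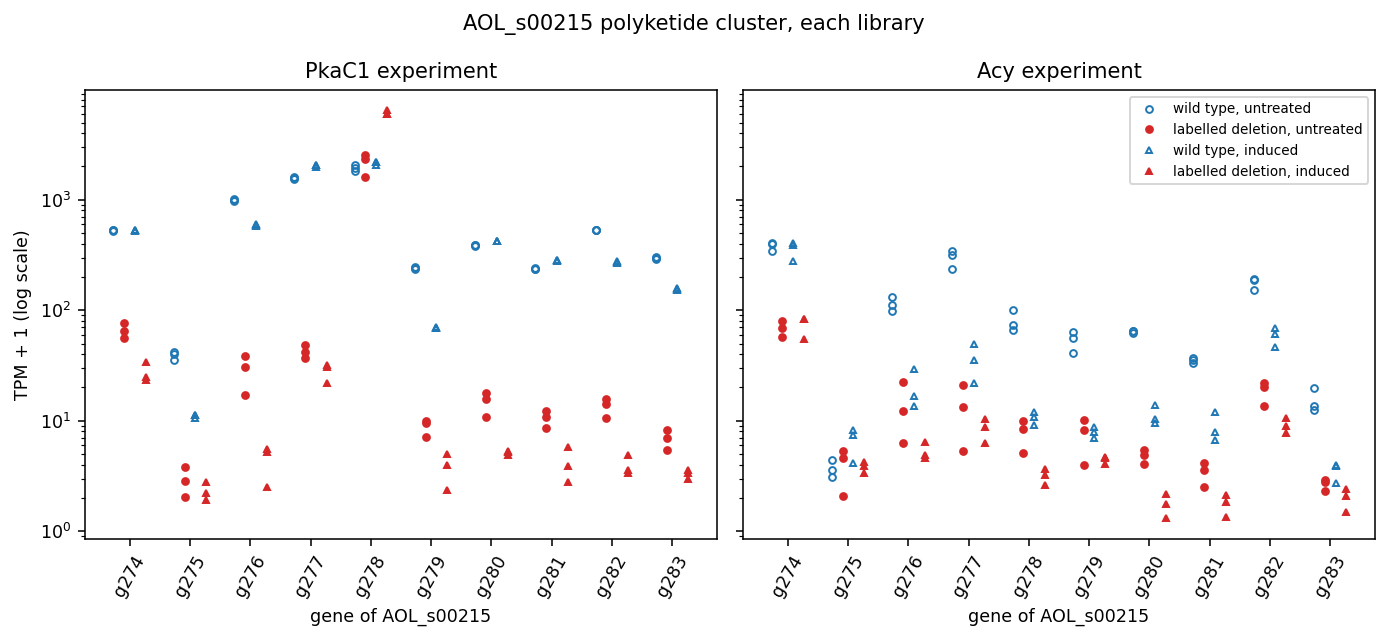
TPM + 1 (log axis) of the 10 genes of the AOL_s00215 polyketide cluster in each library, for the PkaC1 experiment (left) and the Acy experiment (right); open symbols are wild type, filled symbols libraries labelled deletion, circles untreated and triangles induced. All genes but AOL_s00215g278 are lower in the PkaC1 deletion libraries, where that gene reaches 6104 TPM after induction.

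Deletion effects were partly shared between the experiments. Over 8751 genes tested in both, the log2 fold changes of both deletions correlated at r = 0.233 (rho = 0.194) untreated and r = 0.0949 (rho = 0.1) induced, across genes and not over independent replicates. Correlations from single libraries of the same number ran from 0.163 to 0.328 untreated and from 0.0766 to 0.0927 induced. Their SDs, 0.0928 and 0.00877, describe such single sets and are no error of r from all libraries. At 2-fold or more, 327 genes were higher in both deletions untreated against 142 if the calls were independent, 127 lower in both against 46.8, and 174 opposite against 166. Induced, 217 were higher in both against 126, 97 lower against 79.8, and 203 opposite against 288. All overlaps are from the deposited TPM. Scaling turned the balance of the induced 2-fold calls in both experiments, and overlaps were not counted after it. Each deletion was measured in 1 experiment only, against that experiment's wild type. A difference between the deletion effects therefore cannot be told apart from a difference between the experiments or their wild types. A joint fit of all 24 libraries found different effects of both deletions for 4821 genes untreated (2353 with a higher effect in Acy, 2468 in PkaC1, but 2686 and 2405 after scaling, 2774 by 2-fold or more) and for 6899 induced (5600 and 1299, but 2315 and 3285 after scaling, 4850 by 2-fold or more). With the PkaC1 wild type groups as 1 library each these counts were 3187 and 5875. Ribosomal proteins differed in both conditions, with a lower effect in Acy untreated (47 of 78 lower, 1 higher, 50 called when adjusted over the list alone, median -0.64, adjusted p = 2.89e-05, and 0.972 with an estimated correlation). The effect in Acy was higher induced (71 higher, 1 lower, or 13 and 3 after scaling, 73 adjusted over the list alone, median 1.15, adjusted p = 0.00209, and 0.678 with an estimated correlation). The proteasome effect was higher in Acy after induction (46 of 51 higher, none lower, or 33 and 5 after scaling, 47 adjusted over the list alone, median 1.43, adjusted p = 8.3e-06, and 0.675 with an estimated correlation). The glyoxylate effect was lower (8 of 13 lower, none higher, 8 adjusted over the list alone, median -0.59, adjusted p = 8.3e-06, and 0.302 with an estimated correlation).

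The wild types of both experiments did not respond alike to induction. Their log2 fold changes correlated at r = -0.11 over 8751 genes (rho = -0.102, SD of single libraries 0.0574). Wild type and deletion responses within an experiment correlated at r = 0.521 (rho = 0.518) over 8977 genes for PkaC1. For Acy this was r = 0.274 (rho = 0.0789) over 9617 genes. At 2-fold or more 31 genes rose in both wild types against 36.9 expected, 126 fell in both against 72.7, and 182 went opposite ways against 107. The joint fit, run after the correlation had been seen, found a different wild type response for 5580 genes, 2841 higher and 2739 lower in the Acy experiment, but 2832 and 3016 after scaling (3503 in all with the PkaC1 wild type groups as 1 library each), 3529 by 2-fold or more. Of 78 ribosomal protein genes 76 had a lower response in the Acy experiment and none a higher one (76 adjusted over the list alone, median -2.57, camera adjusted p = 8.06e-30, and 0.41 with an estimated correlation). For 94 ribosome biogenesis genes this was 71 against 2 (73 adjusted over the list alone, adjusted p = 7.53e-09, and 0.761 with an estimated correlation). For 30 genes of the tricarboxylic acid cycle it was 22 against 3 (26 adjusted over the list alone, adjusted p = 1.47e-05, and 0.499 with an estimated correlation). Nitrogen use went the other way, with 21 of 24 genes responding higher and 1 lower (22 adjusted over the list alone, adjusted p = 1.79e-06, and 0.41 with an estimated correlation).

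**Figure D5:**
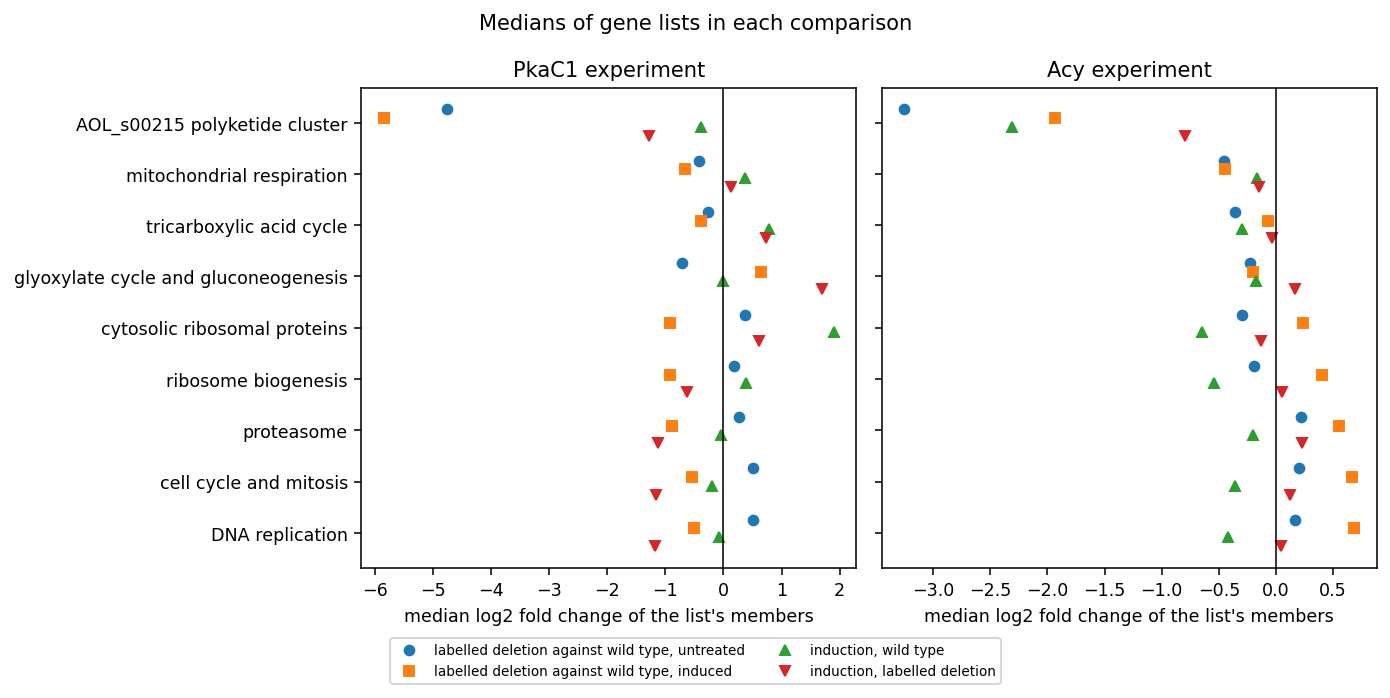
Median log2 fold change of the members of 9 gene lists in each comparison of 2 groups, from the deposited TPM, for the PkaC1 experiment (left) and the Acy experiment (right, the axes differ in range). The medians of the cytosolic ribosomal proteins lie at 1.90 for the induction of one wild type and at -0.64 for that of the other.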

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

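The test of a difference between the wild type responses, the tests on the ribosomal protein genes and the test on the assembled loci were chosen after the result was seen. Counts over splits of the libraries were planned, except that for the wild type responses, a comparison added after the values had been seen.

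The response to induction differed between the PkaC1 deletion and wild type libraries for 6458 genes and between the Acy deletion and wild type libraries for 1852 genes, by limma's test of the difference between groups. Of 100 splits of the same libraries, 1 reached the PkaC1 count, the real one, and the highest other gave 5982 genes with all 3 untreated libraries exchanged between the genotypes. For the Acy experiment 4 of 100 reached the count, and the highest other gave 2885 genes with 2 libraries exchanged in the untreated pair, so a split that mixes the genotypes can call more genes than the real one. Splits that mix the genotypes also carry their difference into the spread between libraries, and the other splits had a median of 0 genes in both experiments. These counts therefore do not decide on chance in the grouping.

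Effects of both deletions differed for 4821 genes untreated and 6899 genes induced in the joint fit. Splits as large numbered 2 and 1 of 100, with 5802 and 4468 genes as the highest others and a median of 0, and for the same reason they do not decide on chance. The highest of the untreated splits exchanged all 3 libraries of the PkaC1 pair, which turns that deletion effect around. Deletion and experiment cannot be told apart in this fit.

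The wild type response to induction differed between the experiments for 5580 genes, with 1 of 100 splits as large, 5552 genes as the highest other and a median of 0, which leaves chance undecided too. That highest other exchanged all 3 libraries of the PkaC1 wild type pair, which turns its response around and mixes no groups. The sum of both responses thus called 5552 genes, so the count of 5580 alone does not show opposite responses. Cytosolic ribosomal protein genes were the list with the lowest p, at a median of 1.90 in one wild type and -0.64 in the other. Scaling of the libraries as the sole source is argued against, since the medians after scaling were 2.12 and -0.419, and the authors' deposited table gives 2.11 and -0.41. Exchanged time labels in 1 experiment might give opposite responses, and the correlation of -0.11 across genes lies too near 0 to decide this; labels and experiment cannot be told apart here. A biological difference between the wild type cultures of both experiments stays open and was not tested.

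Assembled loci without a gene name, outside the main comparisons, held a difference as well. Of 827 such loci tested in the PkaC1 experiment, 208 were higher and 186 lower in the untreated deletion libraries, 112 of them higher by 2-fold or more, and induced 99 were higher and 159 lower. No group had 4 libraries, so single libraries far from their group were not searched for.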

How the results depend on the processing

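Each PkaC1 wild type group taken as 1 library, the assembled loci, and lists without COG text were alternatives chosen after the data were seen. Over 18 counts and correlations and 247 alternative values, 223 stayed within 1.5 times the count or 1 SD, 24 moved and 0 reversed. That SD is the one of single-library correlations, which is no error of r, so for correlations these labels are a rough guide. With each PkaC1 wild type group as 1 library the counts were 3001 (untreated), 3918 (induced), 3343 (wild type induction), 3931 (difference of responses), 3187 (deletion effects between experiments, untreated) and 3503 (wild type responses between experiments), with the spread from the other groups alone. With only the 2 groups compared, induction of the Acy deletion libraries gave 211 genes. Leaving out single libraries gave 152 to 868 genes for that comparison, 1690 to 2263 for induction of the Acy wild type and 851 to 2447 for the Acy difference of responses. The correlation of induced deletion effects was 0.111 with a pseudocount of 0.1, 0.0723 without a filter and 0.0822 to 0.0968 without single replicates, and that of Acy induction responses was 0.299 at a minimum of 5 TPM and 0.244 to 0.264 without single replicates; the cause was not tested.

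Of 105 called lists none passed with an estimated correlation, and 12 were lost by scaling, 3 without COG text, 2 with the replicate block and 2 with 1 library per PkaC1 wild type group. Of the alternative values of 378 gene results 5475 were the same, 27 passed newly, 141 no longer passed and 33 reversed, all 33 among the candidates for the deleted genes and the cluster.

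Scaling reversed AOL_s00078g405 (deletion against wild type, induced) to 0.387 in PkaC1 and -0.337 in Acy; AOL_s00080g284 (wild type induction, PkaC1) to 0.0782; AOL_s00043g480 (Acy) to -0.0934 untreated and -0.17 induced; AOL_s00215g278 (PkaC1, untreated) to -0.105; AOL_s00215g274 to 0.219 (PkaC1) and 0.104 (Acy) in wild type induction, -0.0301 in Acy deletion induction and -0.134 in the Acy difference. It also reversed AOL_s00215g275 to 0.576 (PkaC1) and -0.0879 (Acy) in deletion induction and -0.115 in untreated Acy, AOL_s00215g277 to 0.278 (PkaC1 deletion induction) and AOL_s00215g283 to 0.548 (PkaC1 difference). A pseudocount of 0.1 reversed AOL_s00215g275 to -0.0149 (Acy, untreated). Without single libraries the signs were mixed, with ranges of -0.0764 to 0.201 (untreated) and -0.044 to 0.139 (wild type induction) for AOL_s00043g480 in Acy, -0.06 to 0.287 for AOL_s00078g405 (Acy, induced), -0.00729 to 0.323 for AOL_s00215g278 (PkaC1, untreated) and -0.265 to 0.0263 for AOL_s00215g283 (PkaC1 difference). For AOL_s00215g274 they were -0.014 to 0.00497 (PkaC1 wild type induction), -0.22 to 0.0484 (Acy wild type induction) and -0.0236 to 0.302 (Acy deletion induction), and for AOL_s00215g275 -0.228 to 0.444 (Acy, untreated) and -0.374 to 0.298 (Acy deletion induction). The cause was not tested.

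With the replicate block the 4 PkaC1 comparisons of 2 groups called 5778, 6346, 6222 and 7321 genes and the Acy ones 3879, 5515, 2469 and 349, all within 1.5 times. Outside the untreated and induced Acy deletion libraries, same-numbered libraries share only a number (r = -0.395 to 0.249 in Acy, -0.0871 to 0.0857 in PkaC1). In that pair the NADPH oxidase and melanin list was lost under the block (adjusted p = 0.0435 without it and 0.0556 with it). TPM keep no depth, so what depth limits cannot be given.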

Other observations

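Genes at 10% or less of the wild type mean were searched for, and the tests on replicate spread and on the candidates for the deleted genes were chosen, after the result was seen, except for the test on library-wide shifts; the counts over splits were planned.

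Some genes were listed at 10% or less of the wild type mean in all 6 libraries of a deletion strain. Of 6161 genes at 5 TPM or more in all 6 wild type libraries of the PkaC1 experiment, 16 were at 10% or less of the wild type mean in each deletion library. Among these were 7 genes of the polyketide cluster, an acetyl-CoA acetyltransferase (AOL_s00078g182, from a mean of 2042 to 108 TPM), and 5 genes listed at 0 in all 6, which include argininosuccinate lyase (AOL_s00215g119, 57.2 TPM in wild type), thiamine pyrophosphokinase (AOL_s00210g121, 11.1 TPM) and a dynamitin-domain protein (AOL_s00078g61, 32.3 TPM). An exact 0 in these files can be a failed estimate, so for those 5 genes absence of transcript is not shown. In the Acy experiment 16 of 7139 genes were at this level and 0 of them listed at 0 throughout. They include 2 proteins with a peptidase inhibitor I66 domain, AOL_s00076g558 (455 to 8.62 TPM) and AOL_s00210g28 (360.2 to 4.05 TPM), a protein with a cellulose-binding domain, AOL_s00004g323 (564 to 3.34 TPM), and the lipoxygenase AOL_s00097g288 (196 to 3.88 TPM). In the other direction 26 of 5837 genes and 99 of 7775 genes were at 10% or less in wild type.

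Genes of the cAMP-PKA and G protein list moved both ways and the list was not called in either experiment. In untreated PkaC1 deletion libraries 11 of 22 were higher and 7 lower (18 called when adjusted over the list alone, 7 and 8 after scaling; camera adjusted p = 0.729). Induced, 3 were higher and 11 lower, but 10 and 9 after scaling (14; adjusted p = 0.821). In the Acy experiment 7 of 24 were higher and 4 lower untreated (11; adjusted p = 0.756) and 11 and 1 induced, but 3 and 6 after scaling (12; adjusted p = 0.554).

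Transcript of the candidates for the deleted genes remained in the deletion libraries. An exchange of single libraries between genotypes is argued against by the highest correlation between genotypes at the same time, 0.9127, below the lowest within a group, 0.9714 and 0.968. An exchange of whole groups would leave a candidate deleted in full without transcript in the groups labelled wild type, and is argued against by the lowest mean there, 104% of the deletion group's. Deletion of another gene of the cAMP-PKA and G protein list in full is argued against for the 19 and 22 of 24 members that could be searched, of which 0 were at 10% or less of wild type in all 6 deletion libraries. The other members, and a deletion of part of a member, stay open. The submitters' design text also names a deletion mutant of AorlmA that no sample label carries, and its bearing on the labelled strains was not tested. A deletion of only part of the coding sequence might leave transcript such as the 62.7% of wild type of AOL_s00080g284 in untreated Acy deletion libraries, and 1 value per gene cannot show it. The same gene was at 58.7% in the induced and 149% in the untreated PkaC1 deletion libraries, where it is not the labelled target. For AOL_s00043g480 the induced decrease in TPM (-0.98) and the increase in the authors' deposited table (0.22) stay unexplained.

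The small spread between wild type libraries of the PkaC1 experiment has candidate explanations of which some are argued against. Deeper sequencing of these libraries would matter least for abundant genes, and at 1000 TPM or more the lowest median coefficient of variation of the other groups was still 6.03% against 1.98%. Library-wide shifts are argued against by the 7.1% that remained after scaling, against 2.03% in the wild type. Libraries made from 1 culture or RNA pool could give a spread as low as the 1.98% seen. The submitters' design text speaks of biological replicates, nothing in the sample labels bears on it, and this stays open. No biological explanation was tested.

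For each comparison of 2 groups the 6 libraries allow 10 splits, too few for a share under 0.05, and in each only 1 split, the real one, reached the count. Every other split mixes the 2 groups and carries their difference into the spread between libraries. The low counts of those splits therefore do not decide on chance in the grouping. Deletion against wild type called 5807 and 6368 genes in the PkaC1 experiment (untreated and induced), with 0 and 2 as the highest others, and induction 6258 (wild type) and 7327 (deletion libraries), with 1 and 2. In the Acy experiment the counts were 4051, 5695, 2751 and 480 in the same order, with 0, 0, 0 and 1. Induction of the Acy deletion libraries was the only comparison whose same-numbered libraries all correlated above 0.1, though no label pairs them. Were the numbers pairs, 4 splits would part all pairs, and the highest other among them called 0 genes.

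Exact zeros were frequent in the PkaC1 experiment. There 159 genes were listed at 0 in all 3 libraries of a group and at a mean of 10 TPM or more in another, against 27 in the Acy experiment.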
